A study of Homo sapiens with 9 samples.

How the data were processed

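Messenger RNA was sequenced from OVCAR-8 cells, an established human ovarian cancer line, 48 h after transfection with siRNA. The labels place 9 libraries in 3 groups of 3: a luciferase siRNA as the control, and a pair of siRNAs against CDK12 named CDK12-2 and CDK12-6. Each group has 1 library under each of the numbers AK39, AK41 and AK49, and no label says what these numbers mark. Per the labels, the 3 libraries of a group are technical replicates, so the p-values measure the spread between libraries, which may be technical, and say nothing about spread between separate cultures. The kit named in the labels selects polyadenylated RNA and does not mark strand, so reads of a gene and of an antisense or overlapping partner cannot be told apart.

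The values are RPKM (reads per kilobase of gene length and per 1000000 reads) as deposited by the authors, for 57773 genes with hg19 coordinates. The submitters' processing notes name TopHat2, featureCounts and edgeR and the build hg19, without their order or settings. The version of the gene annotation is not given in the sources used here. The same deposited table holds the authors' log2 fold change and a false discovery rate (an adjusted p-value) for 1 comparison, per the file headers. The header does not say which libraries entered it. Across the tested genes this fold change had a Pearson r of 0.99987 with the log2 ratio of the mean RPKM of the 6 CDK12 siRNA libraries over the 3 controls, so it was read as that comparison.

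Whole reads could be recovered from the deposited RPKM values. Multiplied by the listed gene length plus 1 base, 100% of the values of each library were whole multiples of a single step, within a tolerance of 0.001. The recovered library sizes, in units of 1000000 reads, were 130.7 to 173.4, and 104963048 to 131472019 reads lay in listed genes, or 68.2% to 82.7% of a library. At this depth a gene of 1 RPKM rests on well over 100 reads per kilobase, and the precision of most tested genes is set by the spread between libraries. No pair of libraries was a duplicate: chi-square per degree of freedom between libraries of 1 group was at least 21.2, and between CDK12-2 and CDK12-6 libraries of the same AK number it was 12.6 to 39.1.

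The test planned before the data were examined was a negative binomial model for counts, with limma on log2 values if the unit was a normalized one. Since the unit is RPKM, limma 3.58.1 in R 4.3.3 was used, with eBayes and a trend, on log2(RPKM + 1). Genes with at least 1 RPKM in at least 3 libraries were tested, which left 15208 genes. All 9 libraries and the 3 groups were fitted together, and p-values were adjusted by Benjamini-Hochberg over the tested genes with a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale and understate the change of genes near 1 RPKM. The comparisons were each CDK12 siRNA against luciferase, the mean of both against luciferase, and CDK12-2 against CDK12-6. For genes changed by both siRNAs, which share the 3 control libraries, 100 simulations of unchanged groups gave the overlap and correlation without any effect. All 9 libraries, controls included, were drawn anew from the residuals of the fit, without the AK number.

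Gene lists were fixed before the data were examined. Of 26 lists, 23 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Camera compares the members of a list with all other tested genes, and fry tests the members against no change. Only the preset correlation was tried on simulated lists, so whether camera with an estimated correlation can call a list in this design is not known. Genes were named by a rule fixed at the same time: CDK12, CDK13, CCNK, BRCA1, FANCD2, FANCI and ATR always; the 10 higher and 10 lower genes past the threshold with both siRNAs that had the largest smaller change of both siRNAs, at a mean of at least 1 RPKM and with no overlap between control and CDK12 libraries; the 5 higher and 5 lower for each single siRNA and for CDK12-2 against CDK12-6; and for each list the 2 members that rose and the 2 that fell with the lowest adjusted p, or up to 2 where none passed. Some genes that this rule selects are not used here. Further list members, CD68, COL1A1, single mitochondrial tRNAs and the genes called in the comparison of CDK12-2 with CDK12-6 under other settings were named after their values were seen. The same model was run on a simulation of 100 genes at each of 2 sizes. For the mean of both siRNAs it recovered 61% of genes changed by 0.5 log2 units and 99% of those changed by 1. For CDK12-2 alone it recovered 43% and 91%, and each comparison had 10 false calls among 15208 genes. The simulated noise was independent for each gene, while real libraries share deviations across genes, so these false calls may understate the risk.

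Whether the AK number pairs the libraries was checked from the correlation of deviations from the group means. Between CDK12-2 and CDK12-6 these were 0.76, 0.13 and 0.81 for AK39, AK41 and AK49, so the comparison of both CDK12 groups is also given with the number as a block. Gene biotypes and transcript sequences came from GENCODE release 29, matched by gene identifier for 95.3% of tested genes. Its coordinates were not used, and 11077 tested genes had an annotated 3' UTR. Heptamers in these UTRs were tested against log2 fold changes after regression on UTR length and GC content, with 1000 permutations of the genes. In a simulation, a shift of 0.1 planted in the genes of 1 heptamer was recovered as the lowest in 10 of 10 cases, and a shift of 0.05 in 9 of 10. The spans of 11039 tested genes overlap another listed gene. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, sequences and plots.

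Alternatives planned before the data were examined were the AK number as a block, limma without trend, quantile normalization, no filter, a filter of 5 RPKM, a pseudocount of 0.1, only the groups compared, a minimum log2 fold change of 1, and leaving out libraries. Chosen after seeing the data were voom on the recovered reads, scaling to the reads in listed genes, leaving out the 3 libraries richest in RNA without a poly(A) tail, that RNA as a covariate, the 6 CDK12 libraries as 1 group, and leaving out genes with a named heptamer. Leukocyte, endothelial and erythroid, and fibroblast marker lists had 1, 0 and 1 tested members and were not tested as lists.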

Results

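The study asked how depletion of CDK12 changes gene expression in OVCAR-8 cells, a human ovarian cancer line, using a pair of siRNAs against CDK12 and a luciferase siRNA as the control. RNA was taken 48 h after transfection and 3 libraries were sequenced per group, 9 in all. Between 104963048 and 131472019 reads per library lay in listed genes, and 34233 to 36064 genes had a value above 0. The first principal component of the tested genes held 56.0% of the variance and separated the luciferase libraries from the CDK12 siRNA libraries. The second held 32.8% and had its highest values in luciferase AK41, CDK12-2 AK39 and CDK12-6 AK39. These 3 libraries had the most reads of RNAs without a poly(A) tail in their groups, at 840, 1264 and 1195 per 1000000 reads, against 202 to 737 in the other 6. Deviations of the libraries from their group means also went with transcript GC content, at a Spearman's rho between -0.59 (CDK12-6 AK41) and 0.60 (CDK12-6 AK49).

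CDK12, a kinase that with cyclin K phosphorylates the C-terminal domain of RNA polymerase II, was lower in every CDK12 siRNA library than in every control. Its level was 7.94 ± 0.737 RPKM (SD, n = 3) with luciferase siRNA, 2.44 ± 0.336 with CDK12-2 and 2.40 ± 0.329 with CDK12-6, which is 69.2% and 69.7% lower. The gene (ENSG00000167258) lies on chromosome 17 from 37617764 to 37721160 in hg19. Its log2 fold change was -1.38 ± 0.11 (SE) with CDK12-2 and -1.39 ± 0.11 with CDK12-6 (limma, adjusted p = 5.8e-05 and 5.3e-05). CDK13, the closest relative of CDK12, had 4.73 ± 0.508 RPKM in the controls and 4.95 ± 0.774 over the 6 CDK12 siRNA libraries, and CCNK, the cyclin partner of both, had 6.80 ± 1.06 and 5.78 ± 1.17. Neither passed the test for the mean of both siRNAs (adjusted p = 0.79 and 0.33).

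BRCA1, a central factor of homologous recombination, fell from 2.45 ± 0.078 to 1.38 ± 0.153 RPKM with CDK12-2 and 1.37 ± 0.041 with CDK12-6. Its log2 fold change for the mean of both was -0.54 ± 0.063 (adjusted p = 0.00023). FANCI, a core member of the Fanconi anaemia pathway, fell from 17.4 ± 0.767 to 11.6 ± 0.58 and 11.7 ± 0.39 RPKM (-0.54 ± 0.066, adjusted p = 0.00031). FANCD2, the partner of FANCI, had 3.83 ± 0.186 RPKM in the controls and 3.31 ± 0.36 with CDK12 siRNA (adjusted p = 0.16), and ATR, a checkpoint kinase, had 2.73 ± 0.234 and 2.84 ± 0.141 (adjusted p = 0.66). The annotated 3' UTR of BRCA1 holds GTGGGCA, the heptamer with the lowest z score for log2 fold change among 16193 heptamers tested.

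**Figure D1:**
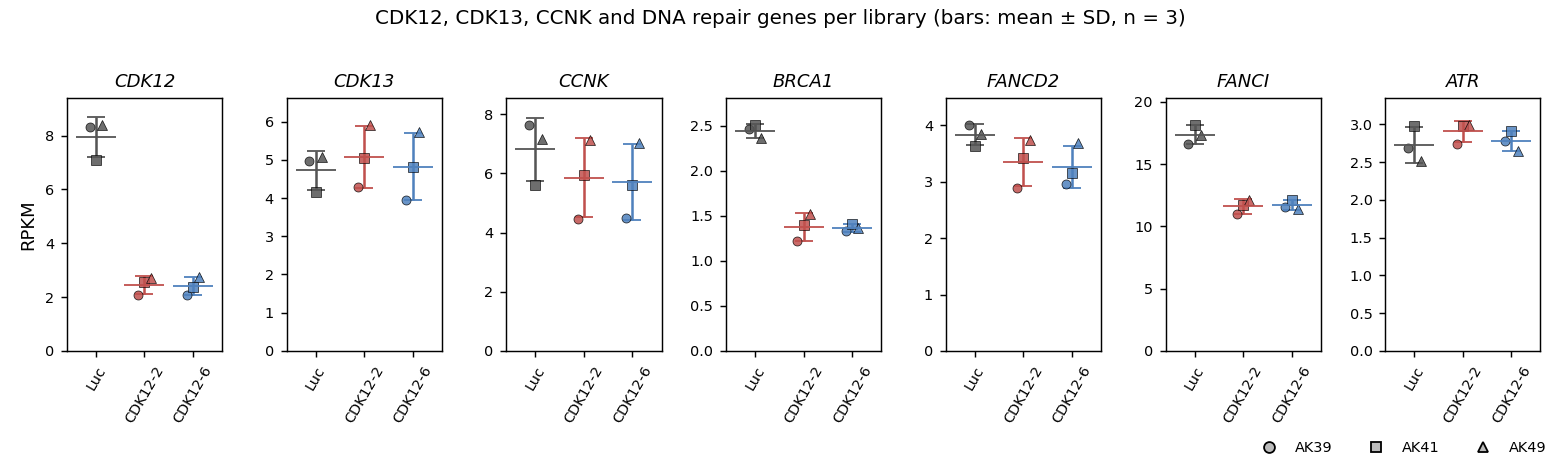
RPKM of CDK12, CDK13, CCNK, BRCA1, FANCD2, FANCI and ATR in each of the 9 libraries, by siRNA group (x axis); markers give the AK number, horizontal lines the group mean and bars the SD of 3 libraries, and each gene has its own y axis from 0. The 6 CDK12 siRNA libraries lie between 2.06 and 2.75 RPKM for CDK12, where the controls lie between 7.09 and 8.40, and the groups also separate for BRCA1 and FANCI.

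The first comparison asked what CDK12-2 siRNA changed against luciferase siRNA. On the log2(RPKM + 1) scale the genes with the largest increase were PPME1, a protein phosphatase methylesterase (8.86-fold in RPKM), GREM1, a secreted BMP antagonist (9.24-fold), P4HA3, a collagen prolyl hydroxylase subunit (7.45-fold), FN1, fibronectin (7.51-fold), and STC2, a secreted glycoprotein (6.17-fold). In plain RPKM the long intergenic RNA RP11-290M5.2 rose more, 11.1-fold, from 0.385 RPKM in the controls. The largest decreases were in CTB-12A17.3, an antisense transcript whose span overlaps CALM3 (log2 fold change -2.42 ± 0.166), PMVK, phosphomevalonate kinase of the mevalonate pathway (-2.13 ± 0.105), CALM3, a calmodulin gene (-2.03 ± 0.129), RRBP1, an endoplasmic reticulum protein (-1.99 ± 0.199), and KRTAP2-3, a keratin-associated protein (-1.97 ± 0.156). In all, 3828 of 15208 genes changed, 1485 higher and 2343 lower. The histone list (16 of 34 members higher), homologous recombination, non-homologous end joining, interferon-stimulated, immediate early, cholesterol and mitochondrially encoded lists passed the list test, and each had an adjusted p = 0.93 with an estimated correlation. Quantile normalization gave 2727 higher and 2803 lower, and scaling to the reads in listed genes gave 2862 and 2633, so the side with more genes depends on the scaling. It also depends on AK39: without CDK12-2 AK39 there were 1841 higher and 1642 lower, and without AK39 in all groups 1233 and 911. The count was 2340 without luciferase AK39, 2550 without luciferase AK49 and 2352 without CDK12-2 AK41, and 2144 and 902 without AK39 or AK41 in all groups.

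The second comparison asked the same of CDK12-6 siRNA. PPME1 (9.74-fold), GREM1 (8.18-fold), P4HA3 (8.08-fold) and FN1 (6.51-fold) again had the largest increases on the log2(RPKM + 1) scale, with RP11-290M5.2, which went from 0.385 ± 0.152 to 4.46 ± 0.314 RPKM (11.6-fold). CTB-12A17.3 (-2.39 ± 0.166), PMVK (-2.19 ± 0.105), ESRG, a transcript within an intron of another gene (-2.06 ± 0.237), RRBP1 (-2.06 ± 0.199) and CALM3 (-2.0 ± 0.129) had the largest decreases. A total of 3961 genes changed, 1584 higher and 2377 lower. Mitosis genes passed the list test here (adjusted p = 0.033), as did histone, homologous recombination, non-homologous end joining, interferon-stimulated, immediate early and cholesterol genes, each with an adjusted p = 0.94 with an estimated correlation. Scaling to the reads in listed genes gave 2803 higher and 2769 lower genes, and leaving out AK39 in all groups 1052 and 929. Leaving out luciferase AK39 gave 2316, luciferase AK49 2533, CDK12-6 AK41 2408, and AK39, AK41 or AK49 in all groups 1981, 953 and 2638.

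The genes changed by both siRNAs were counted next, since the design uses a pair of siRNAs against a single target. PPME1, GREM1, HIST1H2BK and FN1 rose with both, and PMVK, CALM3, CTSZ, UHMK1 and CDK12 fell with both. Of the calls of either siRNA, 3410 were shared in the same direction (1322 higher, 2088 lower) and 0 in opposite directions. This is 89.1% of the CDK12-2 calls and 86.1% of the CDK12-6 calls. Scaling to the reads in listed genes gave 2504 higher and 2425 lower shared genes, so the larger side depends on the scaling here too. Independent lists of these sizes would share 155 higher and 366 lower genes. The 100 simulations of unchanged groups, with simulated controls common to both comparisons, shared 0. Across genes, which are not independent replicates, Spearman's rho of both log2 fold changes was 0.96, where simulated unchanged groups gave a mean of 0.41 and up to 0.98, and the covariance was 0.123 against 0.0072 on average and 0.0385 at most. The 3 controls are too few to split, so part of the excess may come from the shared controls, and the count of genes changed the same way by both siRNAs was 2028 without luciferase siRNA replicate AK39, 2217 without luciferase siRNA replicate AK49 and 2257 without CDK12-2 siRNA replicate AK41.

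**Figure D2:**
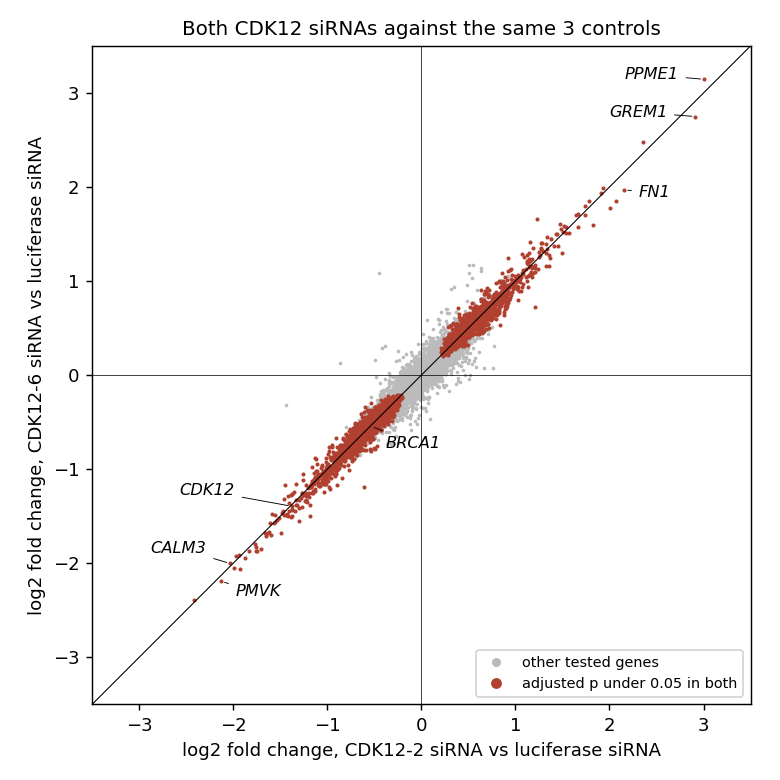
Log2 fold change of 15208 tested genes with CDK12-2 siRNA (x axis) and with CDK12-6 siRNA (y axis), each against the same 3 luciferase siRNA libraries; red points passed an adjusted p of 0.05 in both comparisons, grey points did not, and the diagonal marks equal change. The red points all lie at the lower left and upper right, 2088 lower and 1322 higher with both siRNAs.

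For the mean of both siRNAs against luciferase, PPME1 rose from 9.21 ± 1.07 to 85.6 ± 13.0 RPKM (SD, n = 3 and 6), a log2 change of 3.08 ± 0.13. GREM1 rose from 4.03 ± 0.264 to 35.1 ± 5.31, FN1 from 1.22 ± 0.311 to 8.57 ± 2.79, STC2 from 1.71 ± 0.22 to 9.69 ± 2.08, and ARFRP1, a small GTPase, from 5.66 ± 1.18 to 24.2 ± 6.79. A pair of neighbouring histone genes rose as well, HIST1H2BJ from 2.64 ± 0.463 to 12.8 ± 1.82 and HIST1H2BK from 28 ± 2.64 to 101.1 ± 6.79. P4HA3 (1.84 ± 0.139 to 14.3 ± 2.15) is less certain, because its span on chromosome 11, 73946846 to 74022702 in hg19, overlaps that of PPME1, 73882144 to 73965748. PDCD4-AS1 (0.701 ± 0.153 to 4.84 ± 0.742) is an antisense transcript and uncertain for the same reason, since the kit does not mark strand. RP11-290M5.2 completed the 10 higher genes at 1.96 ± 0.108 on the log2 scale.

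On the log2(RPKM + 1) scale CTB-12A17.3 had the largest decrease, from 152.3 ± 18.3 to 28.2 ± 4.68 RPKM. Its span on chromosome 19 lies within that of CALM3, which fell from 79.7 ± 9.53 to 18.9 ± 2.09 (47112534 to 47114036 and 47104331 to 47114050), so reads of one may be counted for the other. PMVK, with the next largest decrease, fell from 12.8 ± 1.73 to 2.07 ± 0.169, CTSZ, a lysosomal cathepsin, from 75.8 ± 6.45 to 19.4 ± 2.67, and UHMK1, a serine/threonine kinase, from 16.7 ± 1.61 to 4.12 ± 0.267. RRBP1 fell by 2.02 on the log2 scale, ESRG by 2.0, KRTAP2-3 by 1.95, RP11-380P13.2, a long intergenic RNA, by 1.91, and HTATSF1P2, a processed pseudogene, by 1.86. HTATSF1P2 may share reads with its parent gene and KRTAP2-3 with near-identical family members. The annotated 3' UTRs of CALM3, CTSZ, UHMK1 and GREM1 hold GTGGGCAA and that of ARFRP1 holds GTGGGCA. Over all genes, 5024 changed, 2027 higher and 2997 lower, and 97 and 169 of these by at least 1 log2 unit. Scaling to the reads in listed genes gave 3388 higher and 3159 lower. The count was 3095 without luciferase AK39, and 3171 (1784 higher, 1387 lower) and 1805 without AK39 or AK41 in all groups.

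Among CDK12 partners and transcription elongation kinases, 3 of 25 members rose and 3 fell (2 and 3 adjusted over the list alone). HEXIM1, an inhibitor of the elongation kinase P-TEFb, rose from 16.3 ± 1.61 to 29.3 ± 3.67 RPKM, and CCNT2, a cyclin of P-TEFb, from 7.45 ± 0.75 to 9.28 ± 0.491, a call lost in 4 of 19 alternatives. ELL2, an elongation factor, fell from 6.13 ± 0.501 to 1.58 ± 0.056, and AFF4, a scaffold of the super elongation complex, from 14.1 ± 1.46 to 9.79 ± 1.19. The list as a whole did not pass (adjusted p = 0.86), with a median of 0.02, a mean of -0.05 and an upward test. Of 22 cleavage and polyadenylation factors, 3 rose and 5 fell (3 and 5 adjusted over the list alone). CSTF1 (0.32) and CLP1 (0.22, a call lost in 3 of 19 alternatives) rose, and CSTF3 (-0.45) and SYMPK (-0.76) fell, with an adjusted p of 0.83 for the list.

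Homologous recombination genes fell as a list: 13 of 35 members fell and 1 rose (14 and 3 adjusted over the list alone), with a median log2 fold change of -0.19. This list's adjusted p was 0.031, and adjusted p = 0.98 with an estimated correlation. Besides BRCA1, SFR1, an accessory recombination factor, fell from 3.01 ± 0.304 to 1.36 ± 0.087 RPKM and SLX4, a nuclease scaffold, from 2.96 to 1.51, while RMI2 rose from 4.74 ± 0.339 to 6.70 ± 0.866. BRCA2 had 4.01 RPKM in the controls and 3.75 with CDK12 siRNA (adjusted p = 0.55). Non-homologous end joining genes also fell as a list, with 7 of 18 members lower and 0 higher (7 and 0 adjusted over the list alone; adjusted p = 0.031, and adjusted p = 0.98 with an estimated correlation). XRCC6, which encodes Ku70, fell from 134 ± 7.4 to 93.3 ± 4.96, C9orf142, which encodes the Ku-binding factor PAXX, from 27.9 ± 2.82 to 16.5 ± 1.29, and LIG4 from 10.4 to 6.52. Leaving out AK41 in all groups ended both calls (adjusted p = 0.11 and 0.076) at medians of -0.26 and -0.19, where the median of all genes was -0.08, as did quantile normalization (0.072 and 0.083) and leaving out the 3 libraries with the most RNA lacking a poly(A) tail (0.077 and 0.063), and scaling to the reads in listed genes ended that of end joining (0.056). Without genes that hold GTGGGCA in the 3' UTR, among them BRCA1, the recombination list had an adjusted p of 0.18 over 29 members at a median of -0.17, about as low as with them. Members with the heptamer fell more often, 5 of 6 against 8 of 29 without it (Fisher's exact test, p = 0.019, adjusted p = 0.093 over 5 lists).

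The other repair lists moved both ways. In the Fanconi anaemia pathway 3 of 16 members rose, FANCC (0.31) and FANCL (0.22, a call lost in 8 of 19 alternatives) among them, and 5 fell, FANCI and FANCF (-0.45) among them (3 and 6 adjusted over the list alone; adjusted p = 0.47). Of 22 checkpoint genes, WEE1 (0.57) and CDC25C (0.35), regulators of entry into mitosis, rose, and 4 fell (2 and 4 adjusted over the list alone; adjusted p = 0.95). ATM, the kinase that responds to double-strand breaks, was among them and fell from 5.84 ± 0.45 to 3.37 ± 0.153 RPKM, as was TIPIN (-0.47). The 3' UTR of ATM holds GTGGGCA. In excision and mismatch repair 4 of 33 members rose and 7 fell (4 and 8 adjusted over the list alone; adjusted p = 0.32). ERCC6 (0.40) and ERCC5 (0.30) rose, and ERCC4 (-0.44) and NEIL2 (-0.60), which holds GTGGGCA, fell.

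DNA replication genes had 17 of 46 members lower and 6 higher (19 and 7 adjusted over the list alone), and the list did not pass (adjusted p = 0.54). CDT1, a licensing factor, fell from 21.5 to 9.46 RPKM, CDC45, a helicase component, from 13.1 ± 0.344 to 8.20 ± 0.636, and ORC3, an origin recognition subunit, from 21 ± 3.67 to 10.9 ± 1.16, while MCM2 rose from 36.2 ± 4.28 to 53.4 ± 7.53 and RFC1 from 16.9 ± 1.33 to 20.8 ± 1.15. Mitosis genes rose as a list, with 6 of 34 members higher and 0 lower (5 and 0 adjusted over the list alone; adjusted p = 0.032, and adjusted p = 0.98 with an estimated correlation). CENPF, a kinetochore protein, rose from 13.4 ± 0.164 to 19.9 ± 1.14, CCNB2, a mitotic cyclin, from 39.2 ± 1.1 to 52.3 ± 2.96, and NDC80 from 20.9 to 30, and the list had an adjusted p of 0.14 without AK39 in all groups, 0.092 with non-polyadenylated RNA as a covariate (medians of 0.14 and 0.09 against 0.07) and 0.14 with fry. Of 19 p53 targets, 5 rose, FDXR (0.56) and CCNG1 (0.53) among them, and 4 fell, TP53I3 (-0.49) and AEN (-0.41) among them (5 and 4 adjusted over the list alone; adjusted p = 0.54). CDKN1A, which encodes p21, had 7.45 RPKM in the controls and 7.37 with CDK12 siRNA (adjusted p = 0.92).

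Immediate early genes, which respond to growth factors and stress within minutes, fell as a list: 12 of 21 members fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -0.43. The list's adjusted p was 0.011, and adjusted p = 0.98 with an estimated correlation and 0.075 with fry. DUSP1, a MAP kinase phosphatase, fell from 51.0 ± 5.12 to 20.7 ± 2.54 RPKM, KLF6, which holds GTGGGCA, from 34.3 ± 4.45 to 13.7 ± 2.23, EGR1 from 3.5 to 1.16 and MYC from 32.4 to 23.8. Interferon-stimulated genes rose as a list, with 5 of 16 members higher and 2 lower (6 and 2 adjusted over the list alone; adjusted p = 0.020, and adjusted p = 0.98 with an estimated correlation). IFI6 rose from 4.39 ± 0.243 to 12 ± 1.09, IFIT1 from 0.694 ± 0.072 to 2.44 ± 0.35 and ISG15 from 4.84 to 9.08, while MX2 (-0.42) and IFIT5 (-0.31) fell, calls lost in 3 and 9 of 19 alternatives. Quantile normalization gave this list an adjusted p of 0.074, leaving out AK39 in all groups 0.094, and non-polyadenylated RNA as a covariate 0.064, with medians of 0.21, 0.20 and 0.17 against 0.16, where the median of all genes was 0.01, 0.04 and -0.01 against -0.04. Among 15 NF-kB targets and cytokines, IL1A (0.54) and IL8 (0.58) were among 4 that rose, and CXCL2 (-0.84) fell (4 and 1 adjusted over the list alone; adjusted p = 0.093).

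Genes of cholesterol synthesis and uptake rose as a list, with 10 of 23 members higher and 2 lower (11 and 3 adjusted over the list alone; adjusted p = 0.020, and adjusted p = 0.98 with an estimated correlation and 0.14 with fry). NSDHL, a sterol synthesis enzyme, rose from 11.2 ± 0.84 to 18.5 ± 1.24 RPKM. The 2 members that fell, PMVK (-2.16) and MVD (-0.34, with GTGGGCA in its 3' UTR), encode consecutive enzymes of the mevalonate pathway; the call of MVD was lost in 7 of 18 alternatives. In the unfolded protein and integrated stress response list 2 of 24 members rose, DDIT4 (0.58) and DNAJB9 (0.56), and 9 fell (2 and 9 adjusted over the list alone; adjusted p = 0.29). DDIT3, which encodes CHOP, fell from 16.2 ± 1.17 to 8.44 ± 0.458, ASNS, asparagine synthetase, from 4.73 ± 0.423 to 2.62 ± 0.171, and ATF4, a regulator of both, from 109.7 to 71.6. Of 16 NRF2 targets, GCLC (0.33) rose and 6 fell, OSGIN1 (-0.45) and TXNRD1 (-0.39) among them (1 and 6 adjusted over the list alone; adjusted p = 0.44).

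In the BCL2 family, which controls apoptosis, 2 of 16 members rose and 4 fell (3 and 4 adjusted over the list alone; adjusted p = 0.88). The pro-apoptotic BIK rose from 1.55 ± 0.191 to 4.05 ± 0.348 RPKM and BCL2L11, which encodes BIM, from 1 ± 0.115 to 1.85 ± 0.275. The anti-apoptotic BCL2L2, whose 3' UTR holds GTGGGCAA, fell from 12 ± 0.838 to 3.77 ± 0.575. The pro-apoptotic BAD also fell, from 30 ± 1.35 to 21.5 ± 1.27. Epithelial and ovarian carcinoma markers had EPCAM (0.38) and KRT7 (0.47) higher and MSLN, mesothelin (-0.93), lower among 8 tested (2 and 1 adjusted over the list alone; adjusted p = 0.54; median 0.02, mean -0.0044, upward test). Mesenchymal markers moved both ways, with 7 of 17 higher and 6 lower (7 and 6 adjusted over the list alone). FN1 and SNAI2, a transcription factor of the mesenchymal transition that went from 1.83 ± 0.176 to 7.73 ± 1.04, rose, and TAGLN (-0.76) and VIM, vimentin (-0.64), fell. Its median was -0.13, its mean 0.16 and its test upward (adjusted p = 0.58).

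Replication-dependent histone genes, whose main transcripts end in a stem-loop without a poly(A) tail, had 19 of 34 members higher and 0 lower (22 and 0 adjusted over the list alone), with a median of 0.69. The list's adjusted p was 1.7e-09, and adjusted p = 0.98 with an estimated correlation. HIST1H2BK and HIST1H2BJ led, and HIST1H2AG rose from 1.28 ± 0.22 to 5.64 ± 0.3 RPKM; near-identical histone copies may share reads. The RNAs counted as lacking a poly(A) tail are a small set without histones. They took 263, 840 and 352 reads per 1000000 in the luciferase libraries (AK39, AK41, AK49), 1264, 523 and 286 with CDK12-2 and 1195, 737 and 202 with CDK12-6. The median of the histone list was 0.78 without the 3 libraries highest in such RNA, 0.58 with such RNA as a covariate and 0.45 without AK39 in all groups (adjusted p = 0.015). The 13 mitochondrially encoded respiratory chain genes had a median of 0.36, and 0 passed singly (0 adjusted over the list alone). MT-ND2 had 443 ± 92.8 RPKM in the controls and 642 ± 133 with CDK12 siRNA (limma, adjusted p = 0.065), and MT-CO3 had a log2 fold change of 0.50 (adjusted p = 0.073). Each of this pair passed in 1 of the 9 fits without a single library. As a list the mitochondrially encoded genes passed upward (camera, adjusted p = 0.031, and adjusted p = 0.98 with an estimated correlation). The adjusted p was 0.28 after quantile normalization, 0.29 without AK41 in all groups and 0.38 with fry. With each AK number left out in turn, the camera adjusted p ranged from 0.0054 to 0.29. Mitochondrial reads were 1.34% to 1.72% of the control libraries and 2.08% to 2.56% of the CDK12 siRNA libraries.

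The nuclear-encoded respiratory chain had 3 of 63 members higher, NDUFA2 (0.39) and NDUFA8 (0.23, a call lost in 6 of 19 alternatives) among them, and 5 lower, NDUFB4 (-0.42) among them (1 and 3 adjusted over the list alone; adjusted p = 0.94; median -0.02, upward test). Cytosolic ribosomal proteins had 2 of 74 higher, RPL13A (0.32) and RPL29 (0.25), calls lost in 6 and 13 of 19 alternatives, and 5 lower, RPLP0 (-0.39) and RPL10 (-0.29) among them (0 and 1 adjusted over the list alone; adjusted p = 0.88; median -0.01, upward test). Reads of ribosomal protein genes can be shared with their pseudogenes. Markers of other cell types were mostly under 1 RPKM: PTPRC reached at most 0.071 RPKM in any library, VWF 0.132, CD8A 0.793, LYZ 1.20 and PDGFRB 1.26. CD68, which is also found in lysosomes of other cells, had 15.4 RPKM in the controls and 4.54 with CDK12 siRNA, and COL1A1 had 18.2 and 25.

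**Figure D3:**
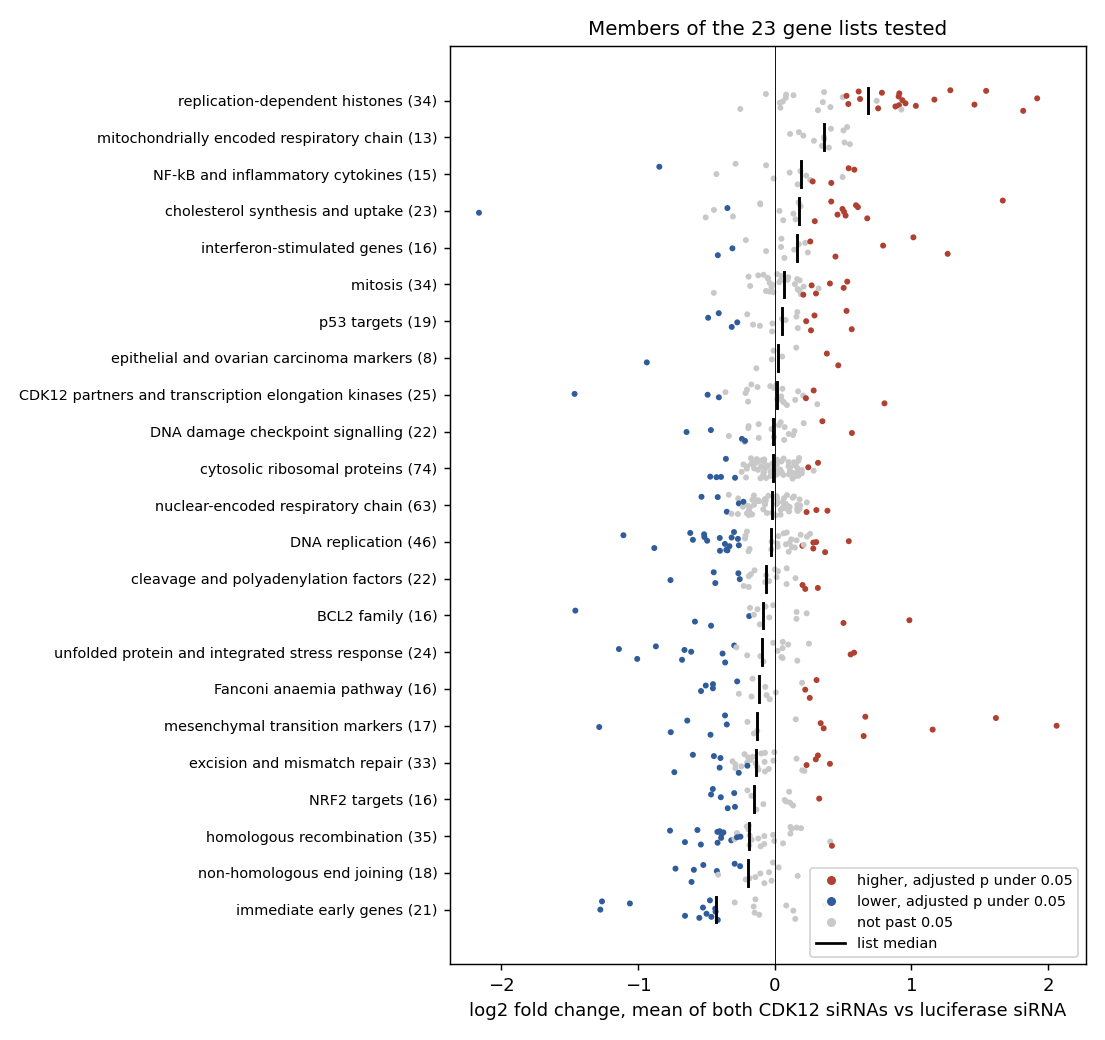
Log2 fold change (x axis, mean of both CDK12 siRNAs against luciferase siRNA) of each tested member of 23 gene lists (y axis, number tested in brackets); points are genes, red and blue where the adjusted p was under 0.05 and grey otherwise, and black bars are list medians. Replication-dependent histones have the highest median (0.69) and immediate early genes the lowest (-0.43).

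The direct comparison asked whether CDK12-2 and CDK12-6 siRNA differ. CDK12 differed by 0.02 on the log2 scale (95% interval -0.25 to 0.29), BRCA1 by 0.01 (-0.17 to 0.18), PPME1 by -0.14 (-0.51 to 0.23), GREM1 by 0.17 (-0.17 to 0.50) and PMVK by 0.07 (-0.19 to 0.32). With limma 0 of 15208 genes passed, and 101 had an unadjusted p under 0.05; voom on the recovered reads and limma without trend also gave 0. For 85.5% of genes the whole 95% interval lay within 0.5 log2 units of 0, and for 99.6% within 1. Ribosomal protein genes were lower as a list with CDK12-2 than with CDK12-6, by a median of -0.09 and in each of the 3 AK numbers (adjusted p = 1.7e-13, and adjusted p = 0.89 with an estimated correlation), as were nuclear-encoded respiratory chain genes (-0.07; adjusted p = 5.8e-08, and adjusted p = 0.89 with an estimated correlation). DNA replication (-0.04, adjusted p = 0.0029), interferon-stimulated (-0.03, adjusted p = 0.022) and histone genes (-0.07, adjusted p = 0.041) also passed, with an adjusted p = 0.98, 0.89 and 0.98 with an estimated correlation. With the AK number as a block the unadjusted count was 183 in the fit of all 9 libraries, with 0 genes called, and 1241 in a fit of the 6 CDK12 siRNA libraries, with 1 gene called, AP000304.1 (2.11 RPKM with CDK12-2 and 0.931 with CDK12-6). In that fit the mitochondrially encoded genes, at a median of 0.13, and the mesenchymal markers, at 0.06, also passed as lists (adjusted p = 0.0030 and 0.024, and adjusted p = 0.97 with an estimated correlation).

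CDK12 acts in transcription elongation, so the fold change was set against gene length. Spearman's rho across genes between the log2 fold change for the mean of both siRNAs and the gene span was 0.02, and with the exonic length it was -0.02. Over single CDK12 siRNA libraries against the control mean, the SD of these values was 0.038 and 0.066, so neither lay outside the spread between libraries. The relation was not monotone: in 10 equal groups by gene span the median was 0.0039 for the shortest genes, -0.07 for spans of 3.30 to 13.3 kb and 0.01 for the longest, with 17.3% of the longest higher and 15.8% lower. Genes are not independent replicates, and with a filter of 5 RPKM the value for the span was 0.068.

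The authors' deposited table gives the same named genes in its own comparison: CDK12 had a log2 fold change of -1.73 there (false discovery rate 7.4e-12), BRCA1 -0.85 (2.8e-07), FANCI -0.59 (4.0e-05) and FANCD2 -0.23 (0.20). The authors deposited 8300 genes under a false discovery rate of 0.05, 4074 higher and 4226 lower, and 5324 of these were among the 15208 tested here. Of those, 4375 (82.2%) were also called here in the same direction for the mean of both siRNAs, and 649 genes were called here alone.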

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

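The fits with voom, with scaling to listed genes, with RNA lacking a poly(A) tail left out or as a covariate, without GTGGGCA genes and with the 6 CDK12 libraries as 1 group are tests chosen after the results were seen. Alternatives were run for CDK12, the 99 other genes selected by the naming rule and the lists, not for the further genes named. None of their calls reversed, but the side with more genes did: for the mean of both siRNAs it was 2027 higher and 2997 lower, 1784 and 1387 without AK39, and 3388 and 3159 with scaling to listed genes. CDK12 was lower under every alternative, at -1.46 to -1.35 when single libraries were left out. Of the 99 genes 78 kept their call under every alternative, 17 lost it under at least 1 and 4 gained one. Beyond the losses given beside genes, CSTF1, RMI2, FANCC and RFC1 lost their call in 2 of the 9 fits without a single library. CDC25C and ERCC5 lost theirs in 1 of these fits. Counts are given in the order CDK12-2, CDK12-6, mean of both, and the same way with both. With at least 5 RPKM in 3 libraries they were 1945, 2025, 2619 and 1741, because fewer genes were tested, and with an absolute log2 fold change of at least 1 they were 262, 270, 266 and 235, by construction. With non-polyadenylated RNA as a covariate they were 8729, 8514, 9406 and 7643; the cause was not tested. Leaving out libraries gave 902 to 3483, 953 to 4000, 1805 to 5314 and 2028 to 3222, in fits with fewer libraries. The last range is of single libraries only; without AK41 in all groups that count was not taken and cannot exceed 902. With AK left out in all groups no group had more than 2 libraries.

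CDK12-2 against CDK12-6 gave 0 genes in every leave-one-out fit, 2 without a filter (AL031602.1 and SNRPGP7, both at 0.0644 against 0 RPKM) and 1 without the 3 libraries highest in non-polyadenylated RNA (DAP3P1); the cause was not tested. Of 23 lists, 8 passed for the mean of both siRNAs, 4 after quantile normalization, 0 with camera and an estimated correlation, 4 with fry, and 5 to 8 when an AK number was left out; the cause was not tested. The length trend was 0.0094 to 0.039 without single AK numbers and 0.068 with at least 5 RPKM.

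With the AK number as a replicate block, 5080, 5162, 6241 and 4506 genes changed, and 0 between CDK12-2 and CDK12-6. In that fit MT-ND2 passed at the same log2 fold change of 0.53 (limma, adjusted p = 0.027). Beyond this and the values beside the comparison of CDK12-2 with CDK12-6, the block changed no other call of these genes or lists. Across luciferase and CDK12 libraries the number only hints at pairing: deviations of the same number correlated at -0.56, -0.13 and 0.65 between luciferase and CDK12-2 and at -0.51, 0.47 and 0.75 between luciferase and CDK12-6. Spearman's rho of the deviations with transcript GC content, for luciferase, CDK12-2 and CDK12-6, was -0.55, -0.41 and -0.59 in AK41. It was 0.57, 0.48 and 0.60 in AK49, and 0.29, -0.25 and -0.49 in AK39. The sign was thus the same in all groups for AK41 and for AK49. No alternative adjusted the gene tests for GC content.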

Other observations

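Of the tests in this part, that of different seeds was chosen after the result was seen. So were the fits that leave out or adjust for RNA without a poly(A) tail. The heptamer scan and the counts by gene class were not among the comparisons planned before the data were examined. Of 22 mitochondrial tRNA genes tested, 9 were higher with the mean of both siRNAs, 0 were lower and 13 did not pass, with a median log2 fold change of 0.37. They were not tested as a list. MT-TF rose by 0.85 ± 0.084 (limma, adjusted p = 9.4e-05), MT-TA by 0.82 ± 0.105 and MT-TV by 0.67 ± 0.094. Long intergenic RNAs went both ways, with 88 of 379 higher and 92 lower, as did antisense genes, with 219 of 1417 higher and 236 lower. Protein-coding genes had 1444 higher and 2304 lower of 11160.

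Genes with GTGGGCA in the 3' UTR were lower with both CDK12 siRNAs. CALM3, CTSZ, UHMK1 and BCL2L2 hold the 8-base form GTGGGCAA and fell, while GREM1 holds it and rose. Among 16193 heptamers in 11077 genes GTGGGCA had the lowest z score with CDK12-2 (-12.6) and with CDK12-6 (-12.4), where 1000 permutations reached at most 5.83 and 5.19 in size (permutation p = 0.001 for both, the smallest possible). The permutations shuffle genes, while libraries share deviations across genes, so this p-value does not measure the spread between libraries. Their 95% limit was passed by 18 and 12 heptamers here, and by 41 for CDK12-2 against CDK12-6, where 0 genes changed. On the high side CCTTTCG led with z scores of 5.49 and 5.28 over 276 genes, past the 95% limits of 4.71 and 4.64, which was not explained. GTGGGCA was present in 342 of 1608 genes that fell with both siRNAs (21.3%). Of these, 52 were among the 112 that fell by at least 1 log2 unit (46.4%). It was also present in 96 of 965 that rose with both (9.95%) and in 1076 of 7350 unchanged (14.6%). The difference between genes with and without it was -0.110 to -0.102 in the 6 CDK12 siRNA libraries and -0.0072 to 0.0102 in the controls. Each control was set against the mean of the other controls, which fixes the centre of their values, so only their spread is informative.

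Pairing of a small RNA seed with 3' UTRs predicts a grading by site. The mean of genes with GTGGGCAA less that of genes with GTGGGCA alone was -0.0841 ± 0.0240 (SE), and that of genes with TGGGCAA alone less that of genes with no site was -0.0491 ± 0.00979. Thus siRNA seed pairing with off-target transcripts may account for part of the fall of these genes. The grading is not independent of the scan: GTGGGCA was picked as its lowest heptamer, and TGGGCAA was the next lowest for the mean of both siRNAs (z of -8.73). Of the 210 anagrams 0.476% were as low, GTGGGCA itself, and the next lowest had a mean of -0.0560 against -0.0915. This rank cannot decide on base composition, since GTGGGCA was picked as the lowest of all heptamers. Genes with the heptamer in the 3' UTR only differed from genes without it by -0.112 ± 0.0103. Those with it in the 5' UTR only, 165 genes, differed by -0.0232 ± 0.0246, and those with it in the coding sequence only by -0.0444 ± 0.00924. The fall was thus largest for the 3' UTR. A mark of a gene class is not excluded, since the coding set was also lower and the 5' UTR set is small. The siRNA sequences are not known here, so the seed itself was not compared, and an endogenous small RNA with this seed stays open. The coding sequence of CDK12, the siRNA target, holds GTGGGCAA once. Of 535 genes of like coding length, 46 (8.6%) hold it, so this does not settle which small RNA acted. For BRCA1, ATM, KLF6, NEIL2 and MVD, which hold GTGGGCA and fell, CDK12 loss and seed pairing could both contribute. The 3' UTRs of PMVK, ELL2, AFF4, ERCC4 and CDK12 itself, which fell, hold TGGGCAA without GTGGGCA. So do those of FANCC, ERCC6 and IL1A, which rose, and of FANCD2, which did not pass.

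CDK12-2 and CDK12-6 siRNA differed in 0 genes past the threshold in the fit of all 9 libraries and in 1, AP000304.1, in the blocked fit of the 6 CDK12 libraries, and CDK12, PPME1 and PMVK had nearly the same change with both. That GTGGGCA belongs to the seed of only 1 siRNA is argued against: it was lowest in both comparisons, and its genes differed between the siRNAs by -0.000646 ± 0.0014. Other heptamers had small differences between them: 41 passed the permutation limit in the direct comparison, led by CTCTCCC (z of 6.43, mean 0.0071) and GAGGCCG (z of -5.65, mean -0.0096), which was not explained. This limit comes from shuffled genes and does not hold the spread between libraries. Whether both groups hold the same duplex cannot be told apart: 8.16% of genes had an unadjusted p under 0.05 in the fit of the 6 CDK12 libraries with the AK number as a block and 1.20% in that of all 9, and the test set in advance did not say which fit. A pair of duplexes with a common seed was not tested and may give the same picture. The annotated CDK12 transcript holds GTGGGCA 1 time in the coding sequence and 0 times in its UTRs. Strands of both siRNAs that have this seed and pair fully with CDK12 would thus lie at that 1 place. The siRNA sequences are not known here, so this does not settle it. No pair of libraries was a duplicate.

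Of 34 replication-dependent histone genes, 19 were higher for the mean of both CDK12 siRNAs, HIST1H2BK and HIST1H2BJ among them, 0 were lower and 15 did not pass. The list had an adjusted p = 0.98 with an estimated correlation. Without the 3 libraries richest in RNA lacking a poly(A) tail, the list's median log2 fold change was 0.78, against 0.69 with all libraries. That fit cannot decide on carry-over of such RNA, since it takes out the richest library of each group, controls included. The controls left had 263 and 352 such reads per 1000000, and the CDK12 siRNA libraries left had 202 to 737. Leaving out AK39 in all groups kept the same CDK12 siRNA libraries, with controls at 840 and 352, and the median was 0.45. This argues against carry-over as the whole cause, since these controls were not the poorer in such RNA. Both this value and the 0.58 with such RNA as a covariate were under 0.69, so carry-over may account for part. A change in the polyadenylation of histone transcripts and a shift in the cell cycle stay open and were not tested.

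Other splits of the same libraries gave fewer genes in all comparisons with luciferase. For CDK12-2 the real split gave 3828 and the highest other 1, for CDK12-6 3961 and 0, in each case 1 of 10 splits as large, which are too few for a share under 0.05. For the 6 CDK12 libraries against the 3 controls the real split gave 5552 and the highest other 2364 (luciferase AK41, CDK12-2 AK39 and CDK12-6 AK39), 1 of 84 splits as large. For CDK12-2 against CDK12-6 the count of splits decides nothing, since 10 of 10 must give at least the real 0. The highest other, with both AK39 libraries and CDK12-6 AK41 on 1 side, gave 4043 and ignores the AK number that these libraries share.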
